A study of Mus musculus with 6 samples.

How the data were processed

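Single-nucleus RNA sequencing was read for 6 libraries of C57BL/6J mice: young control, old control and old exercise, each from neocortex and from hippocampus, with 1 library in each of the 6 groups. Per the labels, frozen tissue was homogenised with detergent, Hoechst-positive nuclei were sorted, about 15000 nuclei per library were captured with the 10x Genomics 3′ system, and sequencing was on an Illumina NovaSeq instrument. The title of the series also names spatial data, which were not analysed here. The deposited matrices hold UMI counts per gene and barcode; per the file headers they were written by Cell Ranger 4, and per the submitters' processing notes reads were mapped to mm10. The values bear this out: whole numbers for 27998 genes, with barcodes not yet filtered to nuclei and totals that differ between libraries. Whether intronic reads were counted, the strand setting, the annotation release, the ages, the exercise protocol and the animals per library are not given in the sources used here.

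Everything from the raw matrices on was computed here with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9. A barcode was taken as a nucleus with at least 1000 UMIs, at least 500 genes and under 5% mitochondrial UMIs, which left 10785, 14579 and 23349 barcodes in the young control, old control and old exercise neocortex and 14101, 13392 and 14760 in the hippocampus. The mitochondrial limit removed 24, 11 and 2, and 87, 198 and 96 barcodes. Scrublet, run per library with an expected rate of 0.08, marked 516, 1552 and 28 barcodes of the neocortex and 1460, 1020 and 1157 of the hippocampus as doublets (4.78%, 10.65%, 0.12%, 10.35%, 7.62% and 7.84%), and these were left out. A rate under 0.5% counted as a caller that had not worked, which applied to the old exercise neocortex, so doublets remained there.

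Counts were scaled to 10000 per nucleus and log-transformed. From 2000 variable genes, 30 principal components were computed over all libraries together without integration, and Leiden clustering on 15 nearest neighbours at resolution 1 gave 50 clusters. Clusters were named from 22 fixed marker sets by comparing their 10 leading genes; a name means that a cluster resembles a cell type by these markers. Ambient-like clusters, which were shallow and not led by the markers of a class, mixed clusters and clusters without a clear name entered no class; these choices, among them leaving clusters 17 and 22 unnamed, were made after seeing the clusters. The class of excitatory neurons took in dentate granule, CA1 or subiculum and CA3 neurons. Mitochondrial genes were left out of class totals.

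Within a class the UMIs of a library were summed and normalised to the class total (CPM), with exact Poisson intervals. Shares of nuclei have exact Clopper-Pearson intervals, and a count of 0 is bounded by 3 counts. The log2 ratio of 2 libraries was taken with 0.5 added to the counts, for genes with at least 20 UMIs over both, in classes of at least 30 nuclei in each; its interval is the exact binomial one given the sum of both counts. Age was the old over the young control and exercise the old exercise over the old control library, within a tissue. With 1 library per group no test across conditions, no p-value and no count of changed genes was computed, since nuclei of a library are not replicates. For gene lists the median log2 ratio of the measured members is given with an order-statistic interval and with its percentile among 10000 random lists matched in 20 bins of expression; a list of under 5 measured members got no value, and percentiles below 2.5 or above 97.5 set a list apart.

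All lists, marker sets, comparisons and the rule for named genes were fixed before the data were examined: 34 gene lists, with 14 pairs of a list and its main class. The rule named, per class and comparison, the 2 genes most higher and the 2 most lower by the smaller ratio of the tissues, at least 1.5-fold in both, with at least 50 UMIs and not below the free RNA level (3 per direction in dentate granule neurons), up to 2 highest and 2 lowest members of each main list, and a set of genes given wherever measured, such as C4b, Gfap, Apoe, Fos, Bdnf and Dcx. Predicted genes without a name, mitochondrial, ribosomal protein, haemoglobin and sex-linked genes and pseudogenes were not named. Some genes that the rule names are not reported here. Some lists overlap the marker sets that named the classes: 6 of 23 homeostatic microglia genes, 10 of 27 homeostatic astrocyte genes, 9 of 27 myelin genes, 8 of 18 OPC differentiation genes, 7 of 26 inhibitory synapse genes and 7 of 26 blood-brain barrier genes.

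The free RNA (ambient) profile of a library was taken from barcodes with 10 to 100 UMIs, and its share in a class was estimated from markers of other classes; in oligodendrocyte-like nuclei it was 17.3%, 34.2% and 29.9% in the neocortex and 28.1%, 30.0% and 21.3% in the hippocampus, and in OPC-like nuclei up to 63.9%. To ask whether RNA of striatal spiny neurons could carry the immediate early gene ratios, the profile of striatal spiny neuron-like nuclei of the same library was removed from neocortical excitatory neurons at the median share that striatal genes gave. Gene positions came from GENCODE M21, matched by identifier for 27645 genes (98.7%). Genes counted as lying under another gene when a gene on the other strand overlapped them with over 10 times their UMIs, from 50 UMIs on. Age and exercise ratios were correlated across genes with at least 200 UMIs in every library used, beside 100 simulations without effect.

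Alternatives fixed at the start were 500 or 2000 UMIs as the minimum, doublets kept, each tissue clustered alone, resolution 2, centring on the median gene, equal weight per nucleus, subtraction of the free RNA profile, minima of 1 or 100 UMIs per gene, other minima for the correlations, and thinning. Alternatives chosen after seeing the data were another free RNA profile (barcodes ranked 30001 to 50000), removal of the top 8% of doublet scores, mixed clusters joined to a class, equal weight per cluster, genes under a gene of the other strand left out, centring within 20 bins of gene length, and shares with ambient-like, mixed and unnamed nuclei left out of the whole. The method was tested on simulated data with 200 changed genes in 20 draws: in excitatory neurons of the neocortical age comparison (15558 genes) 95.8% of the intervals held the true ratio, true folds of 1.5, 2 and 4 came back as log2 0.58, 1.0 and 1.99, 5.0% of unshifted lists fell outside the percentiles and 100% of lists shifted by 0.3 were found; in microglia of the hippocampal age comparison (7656 genes) the values were 96.6%, 0.58, 0.99, 1.98, 4.0% and 88.5%. The simulation held no variation between animals.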

Results

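The series asks how exercise acts on the molecular state of the ageing mouse brain. Nuclei of the neocortex and the hippocampus were profiled by droplet single-nucleus RNA sequencing in 3 conditions, young control, old control and old exercise, in C57BL/6J mice. Each combination of tissue and condition was 1 library, so there were no replicates within a group, and no test of a difference between conditions was made. The number of animals behind a library, their ages and the exercise protocol are not given in the sources used here. All values below describe these 6 libraries, and every interval is a 95% interval. Intervals of shares, levels and ratios of single genes cover counting error only. Intervals of medians over genes cover the spread among those genes. None covers variation between animals.

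In the neocortex the young control, old control and old exercise libraries held 82454449, 75731626 and 164909770 UMIs (unique molecular identifiers, 1 per captured transcript). In the hippocampus they held 71365575, 91066742 and 175543765. After filtering, 10269, 13027 and 23321 nuclei of the neocortex and 12641, 12372 and 13603 nuclei of the hippocampus were kept, with median depths of 4265, 2859 and 3646 UMIs and of 2636, 3370.5 and 5757 UMIs. Excitatory neuron-like nuclei had a median of 3134.5, 2041 and 3456 genes in the neocortex and 1728, 2355 and 3516 in the hippocampus; thinned to the same depth, they had 691, 694 and 683 and 702, 704 and 685.5 genes.

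The libraries fell into batches. Of the barcodes of kept nuclei, 98.0 to 100% were found in the barcode list of the partner library when the partners were the 2 control libraries of a tissue or the 2 exercise libraries. Between the other 24 ordered pairs the share was 59.7 to 73.5%. By this measure both exercise libraries stood apart from every control library, so exercise and batch cannot be told apart, whereas the young and old control of a tissue went together.

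Nuclei were grouped into classes named after fixed marker genes, and shares are of all kept nuclei, among them those of no class. In the neocortex, excitatory neuron-like nuclei made up 20.7% (20 to 21.5) of the young control, 14.6% (14 to 15.2) of the old control and 20.7% (20.2 to 21.2) of the old exercise library. Oligodendrocyte-like nuclei made up 13.9%, 11.7% and 10.1% there, and 10.3% (9.78 to 10.8), 24.3% (23.5 to 25.1) and 22.3% (21.6 to 23) in the hippocampus. Microglia-like nuclei made up 4.13%, 2.44% and 1.91% in the neocortex and 1.24% (1.06 to 1.45), 3.77% (3.45 to 4.13) and 4.65% (4.3 to 5.01) in the hippocampus. Astrocyte-like nuclei made up 3.05%, 6.76% and 1.67% in the neocortex and 7.85%, 5.76% and 6.37% in the hippocampus, and inhibitory neuron-like nuclei 6.36%, 4.28% and 4.72%, and 7.86%, 4.92% and 4.75%. Dentate granule neuron-like nuclei made up 16.4% (15.7 to 17), 26.3% (25.6 to 27.1) and 18.2% (17.5 to 18.8) of the hippocampal libraries. Nuclei resembling striatal spiny neurons, which lie outside the neocortex, made up 11.3% (10.7 to 12), 23.4% (22.6 to 24.1) and 2.59% (2.39 to 2.8) of the neocortical libraries, against 6, 0 and 0 nuclei in the hippocampus, where a count of 0 allows up to 0.0242% and 0.0221%. How the regions were dissected is not given in the sources used here, and shares may also follow the sort, the UMI minimum and depth. With a minimum of 2000 UMIs the ratio of old to young control shares of astrocyte-like nuclei in the neocortex went from 2.22 to 0.872, and those of old exercise to old control shares of oligodendrocyte precursor (OPC)-like, oligodendrocyte-like and microglia-like nuclei there from 0.582 to 1.12, from 0.864 to 9.34 and from 0.782 to 17.4. In the hippocampus the age ratio of astrocyte-like nuclei went from 0.734 to 3.55 and the exercise ratio of oligodendrocyte-like nuclei from 0.918 to 2.64. With a minimum of 500 UMIs the hippocampal old to young ratios of oligodendrocyte-like and microglia-like nuclei went from 2.36 to 0.917 and from 3.04 to 0.709. The exercise ratio of microglia-like nuclei went there from 1.23 to 0.336, and that of excitatory neuron-like nuclei in the neocortex from 1.42 to 0.861. With ambient-like, mixed and unnamed nuclei left out of the whole, excitatory neuron-like nuclei made up 32.8%, 21.4% and 45.8% of the neocortical libraries, and the neocortical exercise ratios of oligodendrocyte-like and microglia-like nuclei became 1.3 and 1.18. Under all alternatives 29 of 231 share ratios lay on the other side of 1.

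**Figure D1:**
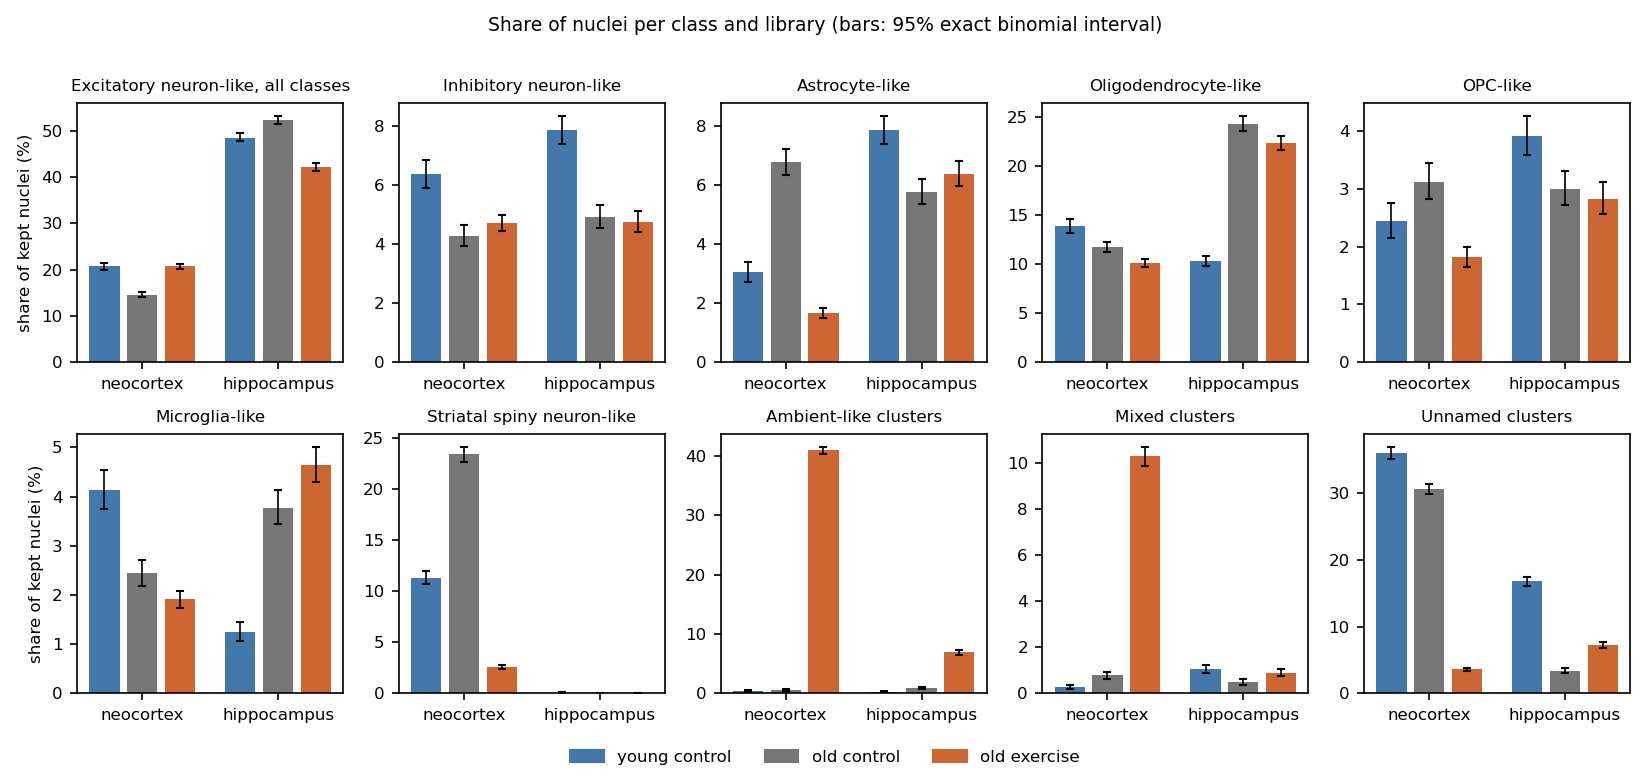
Share of kept nuclei (%, y axis) in each class for the young control, old control and old exercise libraries of each tissue; bars show 1 library each, with the 95% exact binomial interval. Oligodendrocyte-like nuclei made up 10.3% of the young control, 24.3% of the old control and 22.3% of the old exercise hippocampus.

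Several groups of nuclei entered no class. A pair of clusters termed ambient-like, shallower than their libraries (0.77 and 0.31 of the median depth) and led by Pmch or by Rplp1 and Aldoa rather than by the markers of a class, held 0.438%, 0.537% and 40.9% (40.3 to 41.5) of the neocortical nuclei and 0.245%, 0.841% and 6.92% (6.5 to 7.36) of the hippocampal nuclei. Mixed clusters with genes of 2 kinds of cell held 0.263%, 0.783% and 10.3% (9.87 to 10.7), and 1.06%, 0.493% and 0.904%; unnamed clusters held 36%, 30.6% and 3.59%, and 16.8%, 3.41% and 7.29%. The doublet caller marked 28 of 23349 nuclei (0.12%) of the old exercise neocortex, so it had not worked in that library. Within classes the clusters differed too: cluster 2 held 46.8% to 76.2% of the oligodendrocyte-like nuclei of the 4 control libraries, whereas cluster 3 held 68.3% and 81.8% of those of the exercise libraries. Cluster 20 held the largest share of inhibitory neuron-like nuclei in the young control and exercise libraries (30.2% to 37.4%), and cluster 23 in both old control libraries (33.3% and 27.4%).

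Ageing was compared as old control over young control within each tissue. The complement gene C4b was over 10 times higher in oligodendrocyte-like nuclei of the old control: its level was 232 CPM (UMI counts of the gene normalised to the total of the class) against 15.2 in the neocortex (log2 ratio 3.92, 3.49 to 4.42) and 413 against 28 in the hippocampus (3.87, 3.47 to 4.32). Excitatory neuron-like nuclei of the old control held more transcripts of immediate early genes, which neurons switch on within minutes of activity, in both tissues. Microglia-like nuclei held more transcripts of interferon response genes, and oligodendrocyte and OPC-like nuclei fewer transcripts of maturation genes in the neocortex. Respiratory chain genes went different ways in the 2 tissues, without a test of the difference.

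In oligodendrocyte-like nuclei, 16 of 19 measured genes of a disease-associated oligodendrocyte list were higher in the old control hippocampus (median log2 ratio 0.6, above all of 10000 random lists of like expression), and 13 of 19 in the neocortex (median 0.32, percentile 99.3). In the same hippocampal nuclei excitatory synapse genes (31 of 42, −0.18), inhibitory synapse genes (21 of 26, −0.22) and homeostatic astrocyte genes (18 of 26, −0.31) were lower, all at percentile 0. Ribosomal protein genes were higher (76 of 81, 0.32, percentile 100). The percentile is a description of these libraries. When the mixed clusters were joined to the class, the neocortical median was 0.23 and its percentile 95.7. C4b has the identifier ENSMUSG00000073418 (chromosome 17, 34728380 to 34743882, minus strand, mm10). Serpina3n, a serine protease inhibitor of reactive glia, was at 14.1 against 2.82 CPM in the neocortex (log2 ratio 2.26, 1.16 to 3.66) and 28.3 against 5.71 in the hippocampus (2.24, 1.39 to 3.4). Sgk1, a glucocorticoid-induced kinase, was at 166 against 37.7 (2.13) and 160 against 44.5 (1.84), and the alarmin gene Il33 at 420 against 345 (0.28) and 403 against 317 (0.35). Kank1 was lower, at 11.3 against 31.7 CPM (−1.47) and 6.39 against 34.3 (−2.41), as was Nckap5, at 55.8 against 137 (−1.29) and 31.8 against 159 (−2.32). With equal cluster weights the neocortical ratios of Kank1 and Nckap5 were −0.87 and −0.6, and with a minimum of 2000 UMIs −1.74 and −0.55. With free RNA subtracted they were −3.07 and −0.9. Of 27 myelin genes, 26 were lower in the old control neocortex (median −0.54, percentile 0) and 18 in the hippocampus (median −0.04, percentile 10.8). In the same neocortical nuclei genes of other cells were higher, 40 of 42 excitatory synapse genes (0.56, percentile 100) and 20 of 24 homeostatic astrocyte genes (0.93, percentile 100). There free RNA made up an estimated 34.2% of the counts in the old against 17.3% in the young control. With it subtracted the myelin median was −0.39 (percentile 0). Opalin, which encodes a membrane protein of the myelin paranode, was at 282 against 609 CPM in the neocortex (−1.11, −1.25 to −0.98) and 374 against 474 in the hippocampus (−0.34, −0.46 to −0.22).

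In OPC-like nuclei all 16 measured genes of the differentiation list were lower in the old control neocortex (median −0.51, percentile 0), as were 13 of 16 in the hippocampus (median −0.15, percentile 0.9); with doublets kept the hippocampal median was −0.02 and its percentile 32.6. In the neocortex free RNA made up an estimated 48.8% of the counts of these nuclei in the old against 34.5% in the young control. Of 42 excitatory synapse genes, 34 were higher there (0.24, percentile 100). With free RNA subtracted the differentiation median was −0.47 (percentile 0). Gpr17, a receptor of newly committed precursors, was at 299 against 635 CPM in the neocortex (−1.08, −1.3 to −0.87) and 328 against 414 in the hippocampus (−0.34, −0.55 to −0.12). Enpp6, another gene of that stage, was at 21.9 against 68.2 (−1.62) and 49.4 against 70 (−0.5). Rhoj was higher, at 71.3 against 31.3 (1.17) and 65.2 against 36.1 (0.84), and so was Sncaip, at 97.8 against 57 (0.77) and 107 against 30.6 (1.78).

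In microglia-like nuclei 21 of 23 interferon response genes were higher in the old control neocortex (median 0.34, percentile 97.9) and 17 of 20 in the hippocampus (0.55, percentile 100). With a minimum of 500 UMIs the neocortical median was 0.28 (percentile 95.3), and with mixed clusters joined it was 0.1 (percentile 68.7). Rnf213 was at 160 against 83.2 CPM in the neocortex (0.94, 0.42 to 1.48) and 122 against 81.3 in the hippocampus (0.55, −0.21 to 1.48), and Trim30a at 259 against 199 (0.38) and 234 against 119 (0.95). Of the disease-associated microglia genes, 23 of 27 were higher in the hippocampus (median 0.51, percentile 100) and 12 of 26 in the neocortex (−0.07, percentile 14.4). In the same hippocampal nuclei excitatory synapse genes (29 of 38, −0.31, percentile 0), inhibitory synapse genes (18 of 21, −0.37, percentile 0.3) and homeostatic astrocyte genes (12 of 13, −0.7, percentile 0) were lower. Ribosomal protein genes were higher (60 of 79, 0.29, percentile 100). Apoe, a lipid carrier (chromosome 7, 19696109 to 19699188, minus strand), was at 704 against 309 CPM (1.19, 0.93 to 1.45) and 979 against 206 (2.23, 1.78 to 2.76), where the free RNA held 458 against 404 and 613 against 509. Arhgap15 was at 342 against 55 (2.62, 2.12 to 3.19) and 321 against 81.3 (1.94, 1.23 to 2.84). All 23 homeostatic microglia genes were lower in the old control neocortex (median −0.72, percentile 0), against 12 of 23 in the hippocampus (−0.05, percentile 30.5). In the same neocortical nuclei 33 of 37 excitatory synapse genes (0.87, percentile 100) and 19 of 22 inhibitory synapse genes (0.53, percentile 100) were higher. There free RNA made up an estimated 30.8% against 19.9% of the counts. With it subtracted the homeostatic median was −0.55. The purine receptor gene P2ry12 was at 1228 against 2492 CPM in the neocortex (−1.02, −1.17 to −0.88) and 1302 against 1632 in the hippocampus (−0.33, −0.52 to −0.13), and the protease inhibitor gene Cst3 at 4331 against 13338 (−1.62) and 5647 against 5135 (0.14).

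In astrocyte-like nuclei of the hippocampus 17 of 21 reactive astrocyte genes were higher in the old control (median 0.25, percentile 99.8), and in the neocortex 13 of 19 were lower (−0.21, percentile 1.9). With every gene of at least 1 UMI included the neocortical median was 0.23 (percentile 91.5), and with a minimum of 2000 UMIs the hippocampal median was 0.04 (percentile 41.6). In the same hippocampal nuclei inhibitory synapse genes were lower (18 of 25, −0.24, percentile 0) and ribosomal protein genes higher (55 of 81, 0.14, percentile 100). Excitatory synapse genes had a median of −0.04 there (percentile 29.6). Gfap, the intermediate filament of reactive astrocytes, was at 214 against 97 CPM in the hippocampus (1.14, 0.86 to 1.43) and 48.1 against 42.1 in the neocortex (0.18, −0.4 to 0.81). C4b was at 186 against 69.8 (1.41, 1.09 to 1.74) and 118 against 92.1 (0.35, −0.03 to 0.75). Homeostatic astrocyte genes were lower in the neocortex (21 of 27, median −0.15, percentile 0.2), with a median of −0.04 once the free RNA profile was subtracted, and showed a median of 0.05 in the hippocampus. In the same neocortical nuclei excitatory synapse genes (34 of 42, 0.4, percentile 100) and myelin genes (14 of 21, 0.49, percentile 99.9) were higher. So were striatal spiny neuron genes (9 of 9, 0.84, percentile 100), and free RNA made up an estimated 25.7% against 16.3% of the counts. The gap junction gene Gja1 was at 755 against 1099 CPM (−0.54) and 787 against 908 (−0.21). Adgrv1 was at 18.5 against 71.7 (−1.94) and 12.9 against 63.1 (−2.27), and Unc13c at 104 against 257 (−1.31) and 33.1 against 96.3 (−1.53).

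In excitatory neuron-like nuclei 36 of 39 immediate early genes were higher in the old control neocortex (median 0.93, percentile 100) and 32 of 39 in the hippocampus (0.43, percentile 100). Dentate granule neuron-like nuclei, which are part of this class, had a median of 0.07 (22 of 36 higher, −0.05 to 0.26, percentile 94.8). Genes of other cells were also higher in the neocortical nuclei: striatal spiny neuron genes (11 of 12, median 0.78), myelin genes (23 of 27, 0.81) and homeostatic astrocyte genes (17 of 26, 0.61), all at percentile 100. In the hippocampal nuclei homeostatic astrocyte genes (20 of 27, −0.35) and thalamus or habenula genes (8 of 10, −0.68) were lower, both at percentile 0. Myelin genes had a median of −0.03 there (percentile 29.9). Fos (chromosome 12, 85473890 to 85477273, plus strand) was at 36.1 against 4.38 CPM in the neocortex (3.03, 2.68 to 3.41) and 8.42 against 1.79 in the hippocampus (2.21, 1.75 to 2.74). Fosb was at 10.9 against 2.11 (2.36) and 2.67 against 0.807 (1.69), the nuclear receptor gene Nr4a1 at 74.8 against 17 (2.14) and 30 against 12.6 (1.26), and the growth factor gene Bdnf at 56.8 against 43 (0.4) and 90.7 against 63.7 (0.51). Respiratory chain (oxidative phosphorylation) genes went opposite ways: 64 of 73 were lower in the neocortex (−0.16, percentile 0) and 69 of 73 higher in the hippocampus (0.22, percentile 100). Ndufv3 was at 11 against 14.8 CPM in the neocortex (−0.42) and 16 against 17.8 in the hippocampus (−0.16), and Uqcr11 at 15.9 against 16 (−0.01) and 27.7 against 20.3 (0.45). With the free RNA subtracted the hippocampal median was 1.36. Circadian clock genes were higher in the neocortex (18 of 22, median 0.19, percentile 100), with Per1 at 32.4 against 18.1 CPM (0.84) and Bhlhe40 at 20.7 against 12.1 (0.77), and had a median of 0.04 in the hippocampus (percentile 72.7). Excitatory synapse genes had medians of 0.03 and 0.01, and inhibitory synapse genes in inhibitory neuron-like nuclei −0.18 (21 of 26 lower, percentile 0) and 0.02. In those neocortical nuclei myelin genes (21 of 23, 0.43, percentile 100), striatal spiny neuron genes (10 of 12, 0.57, percentile 100) and homeostatic astrocyte genes (11 of 17, 0.26, percentile 99.8) were higher. Ribosomal protein genes were lower there (65 of 81, −0.17, percentile 0).

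In dentate granule neuron-like nuclei Dcx, a microtubule protein of immature neurons, was at 10.4 against 29.9 CPM (−1.52, −1.84 to −1.2). In these nuclei free RNA made up an estimated 14.9% against 15.5% of the counts. Sox11, also of immature neurons, was at 26.5 against 25.3 (0.06). Adamts18 was at 0.464 against 9.9 CPM (−4.33, −5.79 to −3.28) and Col19a1 at 3.58 against 12.6 (−1.81). No cluster was named after newborn neurons, so the neurogenesis list was summed over dentate granule neuron-like and unnamed nuclei of the hippocampus, where it stood at 406.3 CPM in the young control, 244.2 in the old control and 292.6 in the old exercise library. Unnamed nuclei were 2120 of these 4192, 422 of 3681 and 991 of 3463, so the sum also follows their share. In dentate granule neuron-like nuclei alone it was 241.9, 195 and 165 CPM. In the free RNA, which makes up part of these levels, it was 830.9, 420.4 and 618.4 CPM. Like shares of free RNA thus added more of these genes in the young than in the old control. The levels are not given with free RNA subtracted. The lower level of the old control can therefore not be read as a change within these nuclei.

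**Figure D2:**
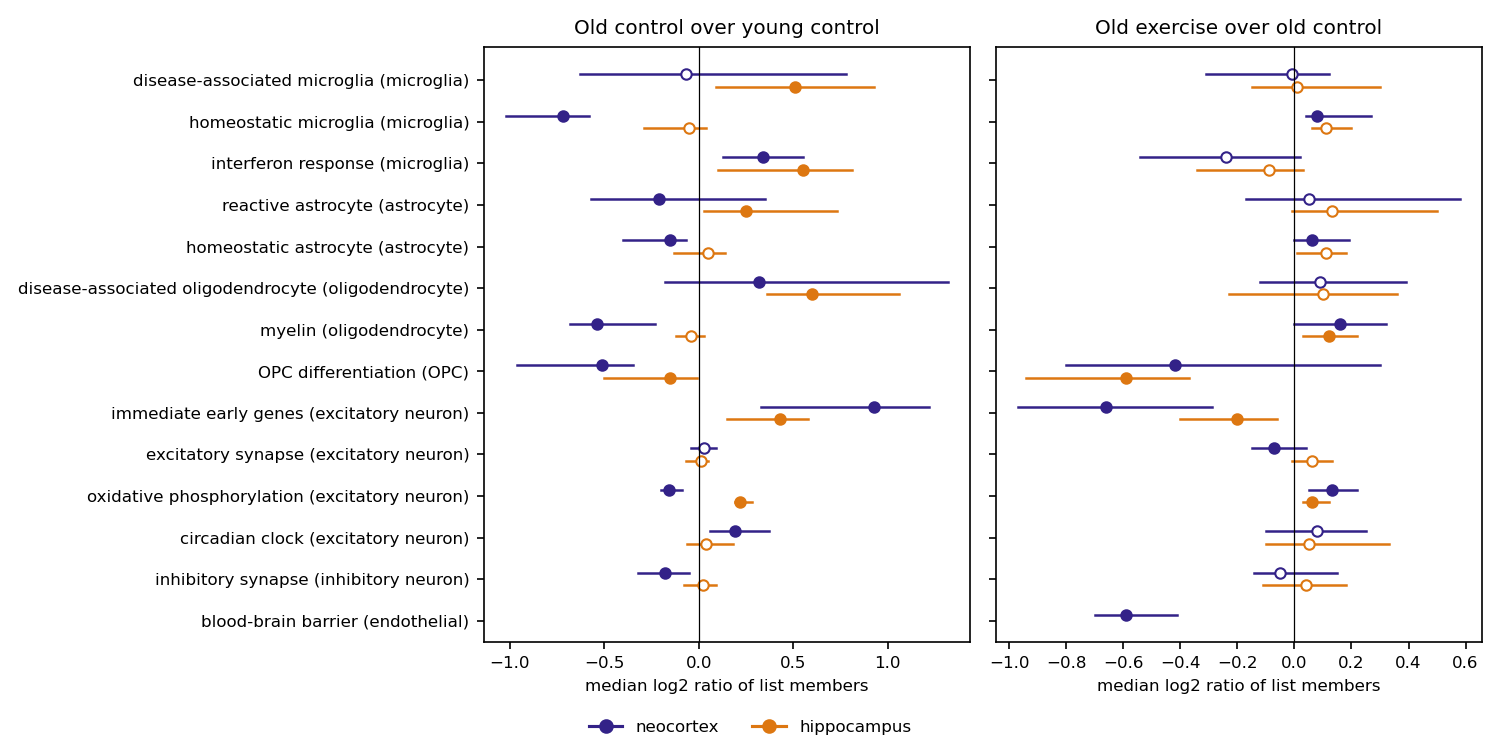
Median log2 ratio (x axis) of the measured genes of each list in its main class, for old control over young control and for old exercise over old control; points are medians with 95% order-statistic intervals, coloured by tissue and filled where the list was set apart from the random lists. Immediate early genes lay at 0.93 and 0.43 in the age comparison and at −0.66 and −0.2 in the exercise comparison.

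Exercise was compared as old exercise over old control within each tissue. Immediate early genes were lower in excitatory neuron-like nuclei of the exercise libraries, with Fos at 11.7 against 36.1 CPM in the neocortex (−1.62, −1.82 to −1.42) and 3.65 against 8.42 in the hippocampus (−1.21, −1.45 to −0.96). OPC differentiation genes were lower in the hippocampus, and respiratory chain genes of excitatory neuron-like nuclei were slightly higher in both tissues. C4b in oligodendrocyte-like nuclei and Apoe in microglia-like nuclei, both higher with age, were not lower in the exercise hippocampus: C4b was at 534 against 413 CPM (0.37, 0.3 to 0.45), and Apoe at 1534 against 979 (0.65, 0.53 to 0.77) beside 1560 against 613 in the free RNA.

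These exercise ratios stand beside a difference of the libraries themselves. Genes lying under a gene of the other strand with over 10 times its counts were lower in the exercise libraries, with medians of −0.2 to −1.24 over the 6 classes compared (for OPC-like nuclei of the neocortex −0.2, −0.4 to 0.02): in excitatory neuron-like nuclei 79.0% of 881 such genes in the neocortex (median −0.81, −0.88 to −0.69) and 82.9% of 1132 in the hippocampus (−1.24, −1.33 to −1.17), against 0.07 and −0.05 in the age comparison, where the other classes had medians of −0.24 to 0.15. How strands were counted is not given in the sources used here, so genes that overlap on opposite strands are uncertain. Among the most lowered named genes, Dnm3os, inside Dnm3, in oligodendrocyte-like nuclei (−2.3 and −2.96) and Pitpnm2os2, over Pitpnm2, in excitatory neuron-like nuclei (−2.23 and −2.78) were of this kind. Fam196b, inside Dock2 on the other strand but not so far below it in counts, was at 106 against 328 CPM (−1.63) and 63.4 against 306 (−2.27) in microglia-like nuclei. Across genes, which are not independent replicates, exercise ratios of the 2 tissues correlated in excitatory neuron-like nuclei with r = 0.76 over 11980 genes and 0.61 without such genes; age ratios correlated with r = 0.13. This is 1 of 6 classes so compared; in the other 5, exercise ratios gave r of 0.38 to 0.58 and age ratios −0.08 to 0.1.

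**Figure D3:**
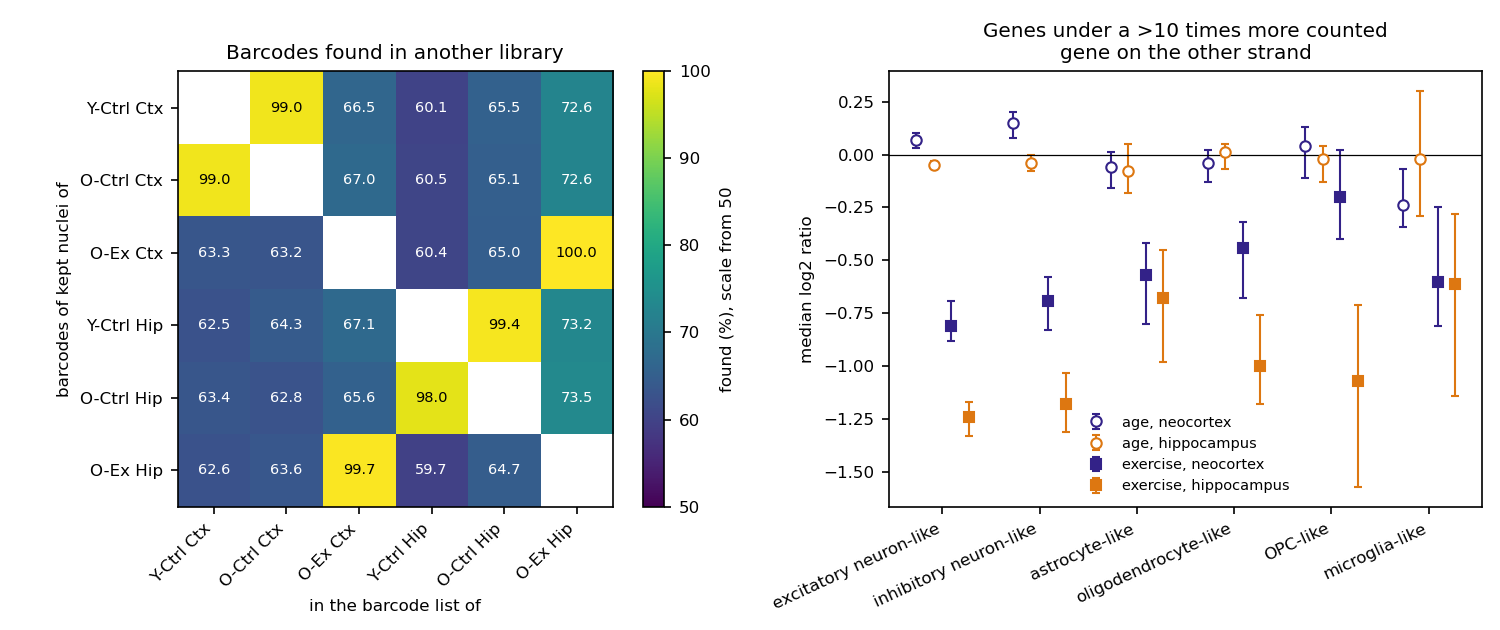
Left, share (%) of the barcodes of kept nuclei of a library (y axis) found in the barcode list of another (x axis). Right, median log2 ratio (y axis, with 95% order-statistic interval) per class of genes lying under a gene of the other strand with over 10 times the counts; exercise values lay at −0.81 and −1.24 in excitatory neuron-like nuclei, age values at 0.07 and −0.05.

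In excitatory neuron-like nuclei 33 of 39 immediate early genes were lower in the exercise neocortex (median −0.66, percentile 0) and 29 of 41 in the hippocampus (−0.2, percentile 0.2). With the free RNA subtracted the hippocampal median was −0.16 and its percentile 25.3, and in dentate granule neuron-like nuclei it was 0.02 (percentile 93.3) without subtraction. Striatal spiny neuron genes were lower in the same neocortical nuclei (11 of 12, median −0.9, percentile 0). Fosb was at 2.58 against 10.9 CPM (−2.09) and 1.31 against 2.67 (−1.03), and Nr4a1 at 34.1 against 74.8 (−1.14, −1.26 to −1.0) and 14.7 against 30 (−1.03, −1.16 to −0.91). Bdnf was at 44.1 against 56.8 in the neocortex (−0.36, −0.5 to −0.22) and 91 against 90.7 in the hippocampus (0.0, −0.06 to 0.07), Homer1 at 412 against 502 (−0.29) and 190 against 188 (0.01), and the neuropeptide precursor gene Vgf at 90.3 against 91.6 (−0.02) and 61.3 against 47.1 (0.38). Of 73 respiratory chain genes, 54 were higher in the neocortex (0.13, percentile 100) and 48 in the hippocampus (0.06, percentile 99.7), and the neocortical median became 0.3 with equal weight per nucleus, the hippocampal one 0.5 with free RNA subtracted. Ribosomal protein genes of the same nuclei had medians of 0.12 (percentile 100) and 0.05 (percentile 99.2). Cox5b was at 19.4 against 13.9 CPM (0.47) and 31 against 20.7 (0.58), whereas Atp5o was at 134 against 253 (−0.92) and 150 against 389 (−1.38). Excitatory synapse genes had medians of −0.07 (27 of 42 lower, percentile 1.4, but 2.8 with doublets kept) and 0.06, with the vesicle fusion gene Snap25 at 1314 against 1100 (0.26) and 1035 against 787 (0.39). Circadian clock genes had medians of 0.08 and 0.05 (percentiles 96.2 and 91.3), with Per3 at 64.7 against 41.8 (0.63) and 58.5 against 46.7 (0.33). Krt20 was at 8.16 against 30.9 (−1.92) and 1.94 against 10.6 (−2.44).

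In inhibitory neuron-like nuclei synapse genes had medians of −0.05 and 0.04 (percentiles 16.8 and 50.7). In the neocortical nuclei myelin genes were higher (25 of 27, 1.19, percentile 100) and striatal spiny neuron genes lower (10 of 12, −0.68, percentile 0). There free RNA made up an estimated 26.8% against 19.5% of the counts. Gphn, the scaffold of inhibitory synapses, was at 1391 against 898 CPM in the neocortex (0.63, 0.56 to 0.7) and 1383 against 910 in the hippocampus (0.6, 0.55 to 0.66), and Pvalb, of fast-spiking interneurons, at 45.2 against 25.3 (0.82) and 43.2 against 24.5 (0.82). The peptide gene Sst was at 972 against 2328 (−1.26) and 1358 against 1195 (0.18), in nuclei whose leading cluster differed between the libraries.

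In oligodendrocyte-like nuclei the disease-associated list had medians of 0.09 (12 of 20 higher, percentile 89.4) and 0.1 (13 of 23, percentile 97.1). C4b was at 234 against 232 CPM in the neocortex (0.01, −0.13 to 0.16). The lipid carrier gene Apod was at 1721 against 1176 (0.55, 0.49 to 0.61) and 1990 against 1271 (0.65, 0.61 to 0.69), Serpina3n at 18.7 against 14.1 (0.39) and 48.1 against 28.3 (0.76), and the protease gene Klk6 at 28.4 against 60.5 (−1.1) and 27.5 against 25.6 (0.1). Of 27 myelin genes, 20 were higher in each tissue (medians 0.16 and 0.12, percentiles 100 and 98.9), among them the transcription factor gene Sox10 at 325 against 175 (0.89) and 270 against 217 (0.32). With clusters weighted equally these medians were 0.0 and 0.02, and with the mixed clusters joined the neocortical one was −0.5. In the same nuclei ribosomal protein genes were higher in the neocortex (71 of 81, 0.26, percentile 100) and lower in the hippocampus (61 of 81, −0.15, percentile 0). Striatal spiny neuron genes were lower in the neocortex (10 of 11, −1.28, percentile 0). In OPC-like nuclei, 11 of 16 differentiation genes were lower in the neocortex (−0.42, percentile 0.1; −0.07 with free RNA subtracted, percentile 44.6) and 15 of 17 in the hippocampus (−0.59, percentile 0). Enpp6 was at 27.4 against 21.9 CPM (0.3, −0.42 to 1.13) and 8.76 against 49.4 (−2.47, −3.36 to −1.69), and Pik3r3 at 121 against 122 (−0.02) and 81.7 against 285 (−1.8).

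In microglia-like nuclei interferon response genes had medians of −0.24 (17 of 25 lower, percentile 2.8) and −0.09 (20 of 29, percentile 25.8), with Trim30a at 190 against 259 CPM (−0.45) and 190 against 234 (−0.3). Disease-associated genes had medians of −0.01 and 0.01, and homeostatic genes 0.08 (18 of 23 higher, percentile 98.9) and 0.11 (18 of 23, percentile 90.2). With mixed clusters joined the neocortical homeostatic median was −1.05. In the same neocortical nuclei ribosomal protein genes (63 of 80, 0.27, percentile 100) and myelin genes (17 of 23, 0.36, percentile 99.7) were higher. Striatal spiny neuron genes were lower there (9 of 9, −1.41, percentile 0). P2ry12 was at 1319 against 1228 (0.1) and 1353 against 1302 (0.05), the transcription factor gene Sall1 at 216 against 309 (−0.52) and 227 against 325 (−0.52), and the lysozyme gene Lyz2 at 126 against 67 (0.89) and 133 against 85.6 (0.63). The neocortical Lyz2 ratio turned to lower with mixed clusters joined. Apoe was at 608 against 704 in the neocortex (−0.21, −0.41 to −0.01).

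In astrocyte-like nuclei reactive genes had medians of 0.05 and 0.13 (percentiles 84.1 and 97.1), with Gfap at 50 against 48.1 CPM (0.05) and 199 against 214 (−0.11) and C4b at 85 against 118 (−0.47) and 194 against 186 (0.06). Homeostatic genes had medians of 0.06 (19 of 26 higher, percentile 97.8) and 0.11 (20 of 27, percentile 96.6); the neocortical median was 0.01 with free RNA subtracted (percentile 82.9) and −0.78 with mixed clusters joined. Glul, which makes glutamine, was at 569 against 388 (0.55) and 505 against 427 (0.24), and the adhesion gene Hepacam at 556 against 363 (0.61) and 469 against 377 (0.32). The neocortical Hepacam ratio turned to lower with mixed clusters joined. Blood-brain barrier genes of endothelial-like nuclei could be compared only in the exercise neocortex, where 23 of 25 were lower (−0.59, −0.7 to −0.41, percentile 0). This was over 67 against 32 nuclei, in which free RNA made up an estimated 50.1% and 60.8% of the counts. In the same nuclei excitatory synapse genes (31 of 37, 0.43, percentile 100), myelin genes (12 of 14, 0.5, percentile 94.4) and ribosomal protein genes (49 of 77, 0.16, percentile 100) were higher. In dentate granule neuron-like nuclei Dcx was at 14.3 against 10.4 CPM (0.46, 0.19 to 0.74), Sox11 at 25.1 against 26.5 (−0.08), Hist1h4d at 3.31 against 0.994 (1.7) and Fshr at 0.461 against 6.83 (−3.83).

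**Figure D4:**
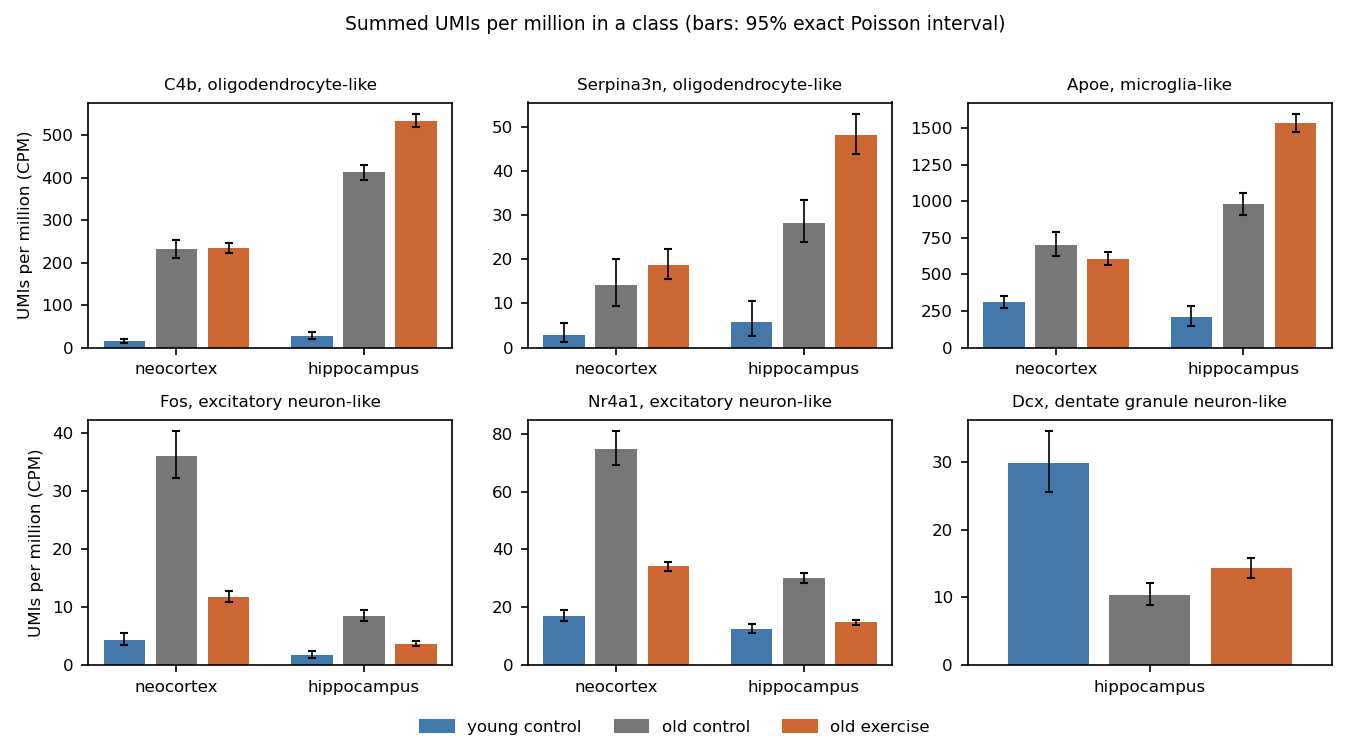
Summed UMIs normalised to the class total (CPM, y axis) of named genes in a class for the young control, old control and old exercise libraries of each tissue; bars show 1 library each, with the 95% exact Poisson interval. C4b in oligodendrocyte-like nuclei lay at 15.2, 232 and 234 in the neocortex and at 28, 413 and 534 in the hippocampus, and Dcx in dentate granule neuron-like nuclei at 29.9, 10.4 and 14.3.

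Set directly against the young control, the exercise libraries held more C4b and Serpina3n in oligodendrocyte-like nuclei in both tissues. C4b in oligodendrocyte-like nuclei was at 234 against 15.2 CPM in the neocortex (3.93, 3.51 to 4.42) and 534 against 28 in the hippocampus (4.24, 3.85 to 4.69), Serpina3n had log2 ratios of 2.65 and 3.01, and the disease-associated oligodendrocyte list had medians of 0.39 and 0.87. The immediate early gene list had medians of 0.29 (−0.03 to 0.5) and 0.18 (−0.02 to 0.28) in excitatory neuron-like nuclei, both at percentile 100, with Fos log2 ratios of 1.41 and 1.01. OPC differentiation genes had medians of −1.16 and −0.61, myelin genes −0.25 and 0.09, and homeostatic microglia genes −0.71 and 0.01. These medians were taken without subtraction of free RNA. It made up 63.9% of the counts of OPC-like nuclei in the exercise against 34.5% in the young control neocortex. In the hippocampus the estimates were 19.7% against 39.9%, and 24.3% against 33.6% by the other profile. All these ratios also set libraries of different batches against each other.

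Whether exercise ratios ran against age ratios was read across genes. In excitatory neuron-like nuclei r was −0.46 over 6167 genes in the neocortex and −0.12 over 9802 in the hippocampus. Both ratios hold the same old control library, and simulated data without any effect gave −0.76 and −0.49 from counting error alone; the covariances were −0.03 against a simulated −0.0047, and −0.0117 against −0.0022. Pairs that share no library gave −0.21 for neocortical age against hippocampal exercise ratios and 0.11 for the reverse, so the sign was not the same in both. In the same order, the other classes gave −0.41, −0.1, −0.2 and 0.19 in inhibitory neuron-like nuclei (simulated −0.75 and −0.56 where the library is shared), −0.2, −0.17, 0.03 and 0.04 in oligodendrocyte-like nuclei (−0.66 and −0.41), −0.1, −0.14, 0.05 and −0.12 in microglia-like nuclei (−0.68 and −0.35) and −0.24, −0.22, −0.09 and 0.09 in astrocyte-like nuclei (−0.43 and −0.56). OPC-like nuclei gave 0.35, −0.17, 0.2 and −0.32 (simulated −0.62 and −0.57). Since r also depends on the spread of the ratios, covariances are given as well. The simulation held counting error only. Any other deviation of the shared old control library enters both ratios with opposite sign and also lowers the covariance. A covariance below the simulated one therefore does not show that exercise ran against age. In the neocortex they were −0.0254 (simulated −0.006) in inhibitory neuron-like, −0.018 (−0.0058) in oligodendrocyte-like and −0.0177 (−0.0035) in astrocyte-like nuclei. Microglia-like nuclei had −0.0139 (−0.0067) and OPC-like 0.0426 (−0.006). In the same order the hippocampal ones were −0.0056 (−0.0048), −0.0125 (−0.0021), −0.0133 (−0.005), −0.0108 (−0.0017) and −0.0118 (−0.0053).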

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

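The tests of depth, the other strand, cluster weights, gene length, ribosomal protein genes and the other free RNA profile were chosen only after the result was seen, and the bounds set for the planned subtraction of free RNA also came after.

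Genes lying under a more counted gene of the other strand were lower in both exercise libraries, with medians of −0.81 and −1.24 in excitatory neuron-like nuclei. Depth per nucleus is argued against in the hippocampus: in the 3 classes where an age comparison had a like gap in depth (1.76 to 1.89 times in either direction, beside 1.87 to 2.01 times with exercise), the age medians were 0.07, −0.04 and 0.04 and the exercise medians −1.24, −1.18 and −1.07. In the neocortex, with class gaps of 1.98 times or more, no age comparison of the same class had a like gap. For the total UMIs of a library, with gaps of 1.93 times or more, no age comparison had one either. Depth thus stays open on both counts. Within each library these genes followed the gene they lie under across the 6 classes, with a median r of 0.67 or more, against at most 0.34 when partners were shuffled. Stray reads of the more counted gene, at a rate that differs between library batches, are a candidate explanation. The shuffling cannot tell stray reads from overlapping genes that are truly expressed together. An r within a library also cannot show a rate that differs between batches. An effect of exercise on these genes cannot be told apart from a batch difference, since at least 99.7% of the exercise barcodes were found in the other exercise library.

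Immediate early genes were higher in excitatory neuron-like nuclei of both old control libraries than in the young control and exercise libraries, though dentate granule neuron-like nuclei had medians of only 0.07 with age and 0.02 with exercise. Free RNA is argued against for the age ratios, since with its profile subtracted the lower median of the 2 tissues was 0.52. It is also argued against for the neocortical exercise ratio, which was −0.56. This profile rested on only 37519 UMIs in the young control hippocampus. The other profile gave 0.95 and 0.5 with age in the neocortex and hippocampus and −0.7 in the exercise neocortex. Free RNA stays open for the hippocampal exercise ratio, which went from −0.2 (−0.4 to −0.06) to −0.16 (−0.93 to 0.05). Its interval became wider and its percentile was 25.3. There the other profile gave −0.16 (−0.37 to −0.02). Another mix of neuron clusters is argued against, since with equal cluster weights the lower age median was 0.31 and the exercise medians were −0.58 and −0.21, all set apart from random lists, and so is RNA of striatal spiny neurons in the neocortex, since removing their profile left 0.93 with age and −0.71 with exercise. A rapid response to handling in every kind of cell stays open: with free RNA subtracted medians fell below the 0.1 it needs, from 0.66 to −0.95 (−1.36 to −0.21) in neocortical oligodendrocyte-like and from 0.15 to −0.07 (−0.37 to 0.08) in hippocampal astrocyte-like nuclei, but the bound set beforehand named only 1 profile and left 13 of 24 and 12 of 22 genes, and the other profile gave −0.41 (−1.12 to 0.26) and 0.12 (−0.43 to 0.8). Handling of neurons alone, age, neuronal activity before death and the time from death to freezing stay open and untested.

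Oxidative phosphorylation genes of excitatory neuron-like nuclei stood out because their age ratios were opposite in the 2 tissues, −0.16 in the neocortex and 0.22 in the hippocampus; the difference was not tested. Gene length is argued against, since centring within length left 0.19 in the hippocampus and −0.11 in the neocortex. Free RNA is argued against only as the source of the opposite signs, since its subtraction gave 1.36 and −0.17. The size in the hippocampus moved with it. There the estimated free RNA share of the young control was 32.8% by this profile and 14.7% by the other. How much free RNA adds to the size of these ratios stays open. Ribosomal protein genes, whose messages are also largely cytoplasmic, went the same ways, at −0.13 in the neocortex and 0.26 in the hippocampus, which is consistent with another share of cytoplasmic RNA in the nuclei as a candidate explanation. An effect of age that differs between the regions stays open and untested.

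Reactive astrocyte genes also had opposite age ratios, −0.21 in the neocortex and 0.25 in the hippocampus, and this difference was not tested; with genes of at least 1 UMI the neocortical median was 0.23, and with a minimum of 2000 UMIs the hippocampal one was 0.04. Ambient-like clusters stood out because they held more of the nuclei in the exercise libraries than in the controls of the tissue, 40.9% of the exercise neocortex and 6.92% of the exercise hippocampus, as did mixed clusters of the exercise neocortex, with 10.3%.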

How the results depend on the processing

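The alternatives from the free RNA plateau, the top doublet scores, the mixed clusters, equal cluster weights, genes of the other strand, gene length and the whole of a share were chosen after seeing the data. Of 30 list results set apart, 17 stayed so under all 15 settings that gave a value (9 planned, 6 added). A value counts as reversed only where a list set apart, a gene at least 1.5-fold off with an interval off 0, or a share ratio at least 1.5-fold off turned its direction; other turns count as moved, or as kept inside the interval. Of all list medians under alternatives, 748 of 783 stayed within their interval, 31 moved and 4 reversed, with 33 on the other side of 0; of single genes 3558, 368 and 5 of 3931, with 121; of class shares 141 (within 1.1 times), 86 and 4 of 231, with 29 on the other side of 1. No value came from the minimum of 2000 UMIs for 10 list results, mostly of microglia-like nuclei (under 30 nuclei), from 100 UMIs per gene for 2 of the interferon response, or at all for endothelial-like nuclei with age and in the exercise hippocampus. The cause was not tested for any change below. Microglia-like, OPC-like and endothelial-like values rest on few nuclei, down to 157, 251 and 32 in a library. The minimum of 500 UMIs lay below the median of the free RNA plateau in the exercise neocortex (594) and the exercise hippocampus (663). Many barcodes counted as nuclei of these libraries at that minimum were therefore at the depth of empty droplets.

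Minimum of 500 UMIs: 48956 (nuclei per library, O-Ex_Ctx, the exercise neocortex), 22640 (nuclei per library, O-Ctrl_Hip, the old control hippocampus) and 74378 (nuclei per library, O-Ex_Hip, the exercise hippocampus); classes with a higher share 1 of 9 (age, hippocampus), 0 of 8 and 0 of 9 (exercise, neocortex and hippocampus); share ratios of oligodendrocyte-like and microglia-like nuclei with age in the hippocampus 0.917 and 0.709, both reversed; blood-brain barrier −0.72. Minimum of 2000 UMIs: 8299 (nuclei per library, Y-Ctrl_Hip, the young control hippocampus); higher shares 1 of 7 (age, neocortex) and 6 of 8 (exercise, neocortex); reversed ratios, of those 1.5-fold off, 0.872 for neocortical astrocyte-like nuclei with age and 1.12 for OPC-like nuclei with exercise, beside turns of lesser ratios to 9.34 and 17.4 for oligodendrocyte-like and microglia-like nuclei of the exercise neocortex, to 2.64 for oligodendrocyte-like nuclei of the exercise hippocampus and to 3.55 and 1.84 for astrocyte-like and OPC-like nuclei with age in the hippocampus; in the exercise hippocampus homeostatic microglia 0.27 and interferon −0.39; myelin −0.12 with age in the hippocampus.

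Ambient-like, mixed and unnamed nuclei left out of the whole: higher shares 5 of 8 and 7 of 9 (exercise, neocortex and hippocampus). Mixed clusters joined, exercise neocortex: disease-associated microglia −0.8, homeostatic microglia −1.05 (reversed), interferon −1.11, reactive astrocyte −0.54, homeostatic astrocyte −0.78 (reversed), disease-associated oligodendrocyte −0.22, myelin −0.5 (reversed), and reversed genes Lyz2 −0.18, Ltc4s −0.32 and Hepacam −0.23; exercise hippocampus: homeostatic microglia −0.17, interferon −0.47; age: homeostatic microglia 0.4 in the hippocampus, interferon 0.1 in the neocortex and 0.98 in the hippocampus, homeostatic astrocyte −0.03 in the neocortex.

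Free RNA subtracted: with age homeostatic microglia −0.55, interferon 0.58 and homeostatic astrocyte −0.04 in the neocortex, oxidative phosphorylation 1.36 in the hippocampus; in the exercise hippocampus homeostatic astrocyte 0.01, oxidative phosphorylation 0.5 and Serpina3n of astrocyte-like nuclei −1.3 (reversed). Plateau profile subtracted: homeostatic microglia −0.53, homeostatic astrocyte −0.03 and oxidative phosphorylation −0.24 with age in the neocortex; oxidative phosphorylation 0.52 (age) and 0.28 (exercise) in the hippocampus; Lars2 of OPC-like nuclei −7.85 in the exercise neocortex (reversed). Other settings: 100 UMIs per gene, interferon 0.02 (exercise, neocortex); 1 UMI, reactive astrocyte 0.23 (age, neocortex; reversed); equal cluster weights, myelin 0.02 (exercise, hippocampus); gene length, oxidative phosphorylation 0.19 and 0.14 (hippocampus, age and exercise); equal weight per nucleus, oxidative phosphorylation 0.3 (exercise, neocortex); tissue clustered alone, blood-brain barrier −0.85.

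Correlations of age with exercise ratios, with a minimum of 50 UMIs: inhibitory neuron-like −0.48 (neocortex), −0.16 (hippocampus) and 0.14 (hippocampal age, neocortical exercise), oligodendrocyte-like −0.3 (neocortex) and 0.1 (hippocampal age, neocortical exercise), OPC-like 0.08 and −0.21 in the same order, microglia-like −0.26 (neocortex). With 1000 UMIs: excitatory −0.42, −0.16 and 0.06 (neocortex, hippocampus, hippocampal age with neocortical exercise), inhibitory −0.5 (neocortex) and −0.15 (neocortical age, hippocampal exercise), astrocyte-like −0.1 (hippocampus), oligodendrocyte-like 0.06 (hippocampus; reversed) and 0.21 (hippocampal age, neocortical exercise), OPC-like 0.15 (neocortex) and −0.45 (hippocampal age, neocortical exercise). Without genes under a gene of the other strand: excitatory −0.51, −0.23 and 0.07 in the order given, inhibitory −0.2 (hippocampus), oligodendrocyte-like −0.28 (neocortex) and −0.05 (neocortical age, hippocampal exercise).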

Other observations

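The tests and gene choices in this part were made only after the result was seen, apart from the gene lists. In astrocyte-like nuclei 20 of 22 measured cholesterol synthesis genes were lower in the old control neocortex (median log2 ratio −0.63, percentile 0) and 23 of 24 in the hippocampus (−0.52, percentile 0); the exercise libraries had medians of 0.34 (20 of 24 higher) and 0.31 (19 of 24 higher) over the old control, both at percentile 100. In the old control neocortex these nuclei also held more transcripts of excitatory synapse genes (34 of 42 higher, 0.4, percentile 100) and myelin genes (0.49, percentile 99.9). Free RNA made up an estimated 25.7% against 16.3% of their counts. Exercise medians were also above 0 in excitatory neuron-like nuclei (0.44 and 0.49), inhibitory neuron-like nuclei (0.35 and 0.29) and oligodendrocyte-like nuclei (0.26 and 0.33), whereas their age medians were −0.13 and −0.2 (percentiles 2.4 and 0), 0.02 and 0.02 (47.8 and 65.8), and −0.06 and −0.26 (6.8 and 0.2). Both ratios hold the same old control library, so opposite signs alone say little. The exercise values carry the same batch as every other exercise value.

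Glucocorticoid response genes were higher with age in oligodendrocyte-like nuclei (21 of 22 in the neocortex, median 0.51, and 18 of 23 in the hippocampus, median 0.5, both at percentile 100) and in excitatory neuron-like nuclei (0.3 and 0.18). Exercise medians in oligodendrocyte-like nuclei were 0.04 and −0.04, and in excitatory neuron-like nuclei 0.06 and 0.01. Zbtb16, a transcription factor gene that glucocorticoids induce, had age ratios of 0.78 and 0.82 in oligodendrocyte-like nuclei. Of the MHC class I genes of hippocampal microglia-like nuclei 8 of 10 were higher with age (median 0.86, −0.1 to 1.79, percentile 100), with H2-D1 at 1.79, B2m at 0.79 and H2-K1 at 0.68. The neocortical median was −0.35 (−0.87 to 0.58, percentile 0.6), and exercise medians were −0.18 and −0.19. The intervals of both age medians spanned no change. Synapse and ribosomal protein genes also moved in these hippocampal nuclei, as given above. In oligodendrocyte-like nuclei the MHC class I medians with age were 0.76 (−0.03 to 1.02) and 0.41 (−0.62 to 1.0).

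PISD was at 315, 1466 and 1658 CPM in excitatory neuron-like nuclei of the young control, old control and old exercise neocortex and at 330, 1418 and 1305 CPM in the hippocampus; the symbol stands in capitals in the files, and GENCODE M21 gave no position for its identifier. Its level on the plateau of empty droplets was 216, 784 and 973 CPM, and 199, 770 and 647 CPM. Gm42418, which overlaps ribosomal RNA sequence, was at 4112, 3553 and 9244 CPM over all kept nuclei of the neocortex and at 3784, 4632 and 10573 CPM in the hippocampus. Haemoglobin gene Hbb-bs was at 5.82, 5.73 and 25.7 CPM in excitatory neuron-like nuclei of the neocortex and 4.25, 6.9 and 31.3 CPM in the hippocampus. Striatal spiny neuron genes had age medians of 0.78 in excitatory neuron-like, 1.0 in oligodendrocyte-like and 1.21 in microglia-like nuclei of the neocortex and exercise medians of −0.9, −1.28 and −1.41. Xist was at 1637, 1514 and 1558 CPM and 1162, 1422 and 1543 CPM, and the Y-linked gene Ddx3y at no more than 0.297 CPM in any library. Choroid plexus-like nuclei made up 0.546%, 0.0242% and 0.154% of the hippocampal libraries.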
